A study of Mus musculus with 14 samples.

How the data were processed

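RNA from mouse carotid arteries was sequenced in 14 libraries, grouped from the sample titles by Rbp7 genotype and treatment into WT DMSO (n = 3), WT rosiglitazone (n = 3), KO DMSO (n = 4) and KO rosiglitazone (n = 4). The design text says that removed arteries were treated, and the treatment protocol says that mice were treated, so whether exposure was in culture or in the animal is not settled by the labels. Per the labels' protocols, total RNA was extracted with Trizol, purified on a column and treated with DNase, and libraries were made by the manufacturer's protocol. The submitters' processing notes name FastQC, kallisto and sleuth and the builds mm10 and GRCm38. Versions, the transcript annotation, trimming and strand settings are not given in the sources used here.

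The authors deposited 1 table of TPM values, 63244 transcripts with UCSC-style identifiers by 14 libraries, in which each library sums to the same fixed total. All 14 columns were matched to samples by the sample number that the labels and the column names share. TPM is a share of each library, so a change in the most abundant transcripts shifts all others, and it keeps no read depth, so no counting interval or detection limit can be given. Values are estimates that divide shared reads among similar transcripts. A transcript listed at 0 can therefore be one to which no reads were assigned, and for groups with such values the value of each library is given in place of a mean.

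No gene symbols are in the table. Its identifiers were compared with the gene name and RefSeq gene tables at hand, and 0 of 63244 matched. Transcripts were therefore not summed to genes, and the 26 gene lists chosen before the data were examined were not tested, because 0 of their genes were found among the identifiers. The level of Rbp7 could not be used to check the genotype labels.

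Transcripts with at least 1 TPM in at least 3 libraries were tested, 29304 in all. Values were log2(TPM + 1), and fold changes are on this scale, which understates the change of low transcripts. One mean per group was fitted over all 14 libraries with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend on abundance. Two-sided moderated tests were made for 6 contrasts: rosiglitazone in WT, in KO and on average, the interaction, and KO against WT in DMSO and in rosiglitazone. Every adjusted p is limma's with Benjamini-Hochberg adjustment over all tested transcripts, with a threshold of 0.05. These models and the alternatives were set before the data were examined, except where said otherwise. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

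The rule fixed for named genes needed gene symbols and named nothing here. It was replaced, after the values had been seen, by the 2 largest changes past the threshold per contrast and direction, or, where none passed, by the 2 smallest p. The named transcripts are thus chosen on their values. Identical rows were kept: 267 tested transcripts fall in 89 sets with the same value in every library.

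The labels number the replicates but do not say whether a number marks an animal or whether replicates came from separate animals, so the p-values measure the spread between these libraries, part of which may be technical. Sample numbers run from 2 to 11 and from 18 to 21, the latter in KO libraries of replicate numbers 3 and 4 only. What the numbers stand for is not given in the sources used here. After 1 split of the KO libraries proved to follow these ranges, the ranges were compared within KO with the same model.

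The tests were checked on simulated data built on 29304 transcripts with 200 changed ones, drawn over all abundances. Values came from a normal spread, independent for each transcript and library, in a single run per contrast. The simulation holds no outlying libraries and no structure by sample number, so the rates below may not hold for the real data. For 4-fold changes the share recovered was 54.5% for rosiglitazone in WT, 68.2% in KO, 81.8% on average, 36.4% for the interaction, and 54.5% and 57.6% for KO against WT in DMSO and rosiglitazone. For 2-fold changes these shares were 16.4%, 29.9%, 44.8%, 11.9%, 22.4% and 11.9%. False calls were 3 of 51, 4 of 74, 12 of 107, 1 of 33, 8 of 61 and 5 of 53 in the same order, above the nominal 5% in 5 of the 6, and no recovered transcript had the wrong sign. Changes of 2-fold would thus mostly be missed.

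Alternatives covered the pseudocount, the filter on low TPM, scaling, the variance model, library weights, fits on the groups of a comparison alone, replicate numbers as a block, sample numbers and leaving out each library. After seeing the data, 4 more were added: removing transcripts over 5000 TPM, merging identical rows, leaving out transcripts listed at 0 in 3 or more libraries, and leaving out both KO libraries of replicate number 4. Other splits of the libraries were counted for every contrast, with at most 100 splits each.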

Results

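Gene expression was measured by RNA sequencing in 14 carotid artery libraries from male C57BL/6J mice that were wild type (WT) or knockout (KO) for Rbp7, the gene of retinol-binding protein 7, a cytosolic carrier of retinoids. The treatment was rosiglitazone, a thiazolidinedione drug that activates the nuclear receptor PPARγ, at 10 µM for 24 h, or the solvent DMSO, and the labels differ on whether removed arteries or mice were treated. WT arteries gave 3 DMSO and 3 rosiglitazone libraries, and KO arteries gave 4 of each. The deposited values are TPM (the share of each transcript, scaled to a fixed total per library) for 63244 transcripts, of which between 37843 and 39006 were above 0 in a library. TPM keeps no read depth, so the depth behind each value is unknown. The files do not pair the transcript identifiers with genes, so transcripts are named by identifier, and the level of Rbp7, which would check the genotype labels, is not reported.

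The libraries were dominated by very few transcripts. The 2 most abundant ones together held between 41.8% and 48.8% of the TPM in 12 libraries. The KO libraries of replicate number 4 had lower shares, 33.2% in DMSO and 37.5% in rosiglitazone. Those 2 libraries also listed the most transcripts at 1 TPM or more, 27686 and 26716, against 23996 to 26179 in the others. On the first principal component, which held 18.4% of the variance, they lay at 93.7 and 57.2, and the other libraries lay between -33.4 and 13.3. Spearman correlations across transcripts had a median of 0.891 over the 18 pairs of libraries within a group and 0.892 over the 73 pairs from different groups, so libraries of a group were no closer to each other by this measure. Transcripts within a library are not independent replicates. Within KO, the 4 libraries with sample numbers 18 to 21, 2 of each treatment, differed from the 4 numbered 2 to 5 in 140 transcripts (63 higher and 77 lower, limma, adjusted p under 0.05), a comparison made after seeing the data.

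**Figure D1:**
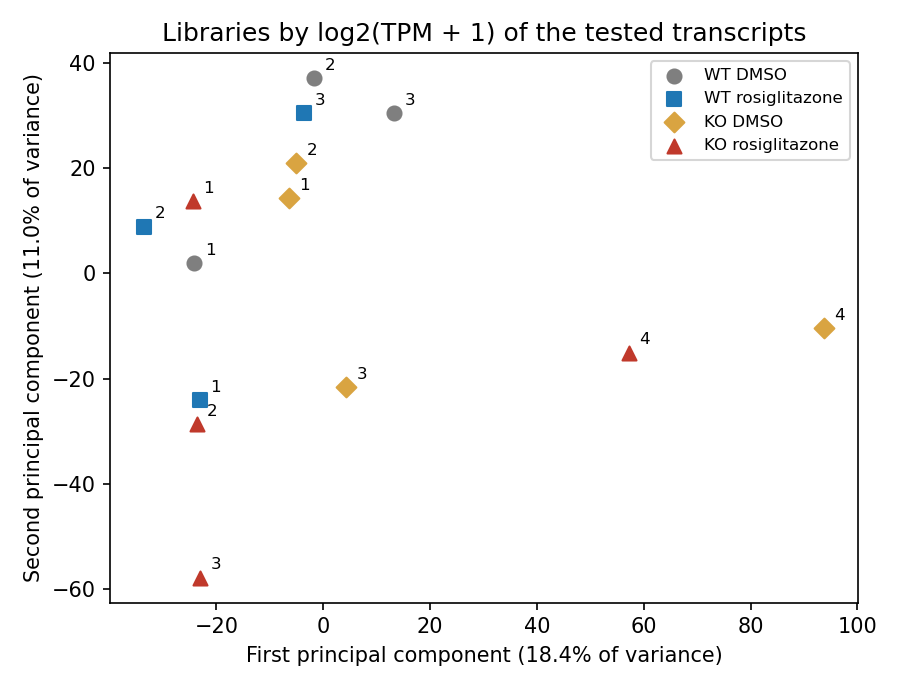
Each point is a library, placed by its first (x axis) and second (y axis) principal component of log2(TPM + 1) over the tested transcripts, in the components' own units; color and shape give the group and the digit the replicate number. The KO libraries of replicate number 4 lie at 93.7 (DMSO) and 57.2 (rosiglitazone) on the first component, to the right of the other 12 libraries.

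The first question was how WT arteries responded to rosiglitazone. Among 29304 transcripts tested with limma, 1 passed an adjusted p of 0.05, and it was lower with the drug. This transcript, uc033hga.1, had 6.33, 13.1 and 10.3 TPM in the WT DMSO libraries and was listed at 0 in all 3 WT rosiglitazone libraries (log2 fold change -3.40, SE 0.32, adjusted p = 0.0022). The higher transcripts with the smallest p did not pass. Among them, uc009saj.1 measured 0.39 ± 0.19 TPM in DMSO (SD, n = 3) and 4.07 ± 0.88 TPM in rosiglitazone (SD, n = 3), a log2 fold change of 1.86 (SE 0.27, adjusted p = 0.0760). The other, uc033jnf.1, was listed at 0 in all 3 DMSO libraries and had 5.60, 10.6 and 5.88 TPM with the drug (log2 fold change 3.01, SE 0.42, adjusted p = 0.0760). The call of uc033hga.1 was lost in 2 of 17 alternative settings, while uc009saj.1 passed in 5 and uc033jnf.1 in 9 of 17. At an unadjusted p under 0.05 there were 1028 transcripts, where 1465 would be expected by chance. Transcripts are not independent, so such a count can stray widely from the expected one. It also moved with the fit. It was 1585 when only the WT groups were fitted (5 calls) and 2031 with library weights (5 calls). Without the KO libraries numbered 18 to 21 it was 1490 (7 calls, fewer transcripts tested). It was 987 with a pseudocount of 0.1 and 744 without WT DMSO replicate 3. Median-of-ratios scaling and quantile normalization each gave 2 calls, 1 higher and 1 lower. The count was 3 without WT DMSO replicate 1 or without WT rosiglitazone replicate 3. It was 2 without WT DMSO replicate 3, WT rosiglitazone replicate 1, KO DMSO replicate 1 or 4, or KO rosiglitazone replicate 4.

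In KO arteries, 4 transcripts passed the threshold for rosiglitazone against DMSO, 2 higher and 2 lower. The same pair seen in WT moved the opposite way. Transcript uc033hga.1 was listed at 0 in all 4 KO DMSO libraries and had 9.24, 3.58, 3.24 and 7.18 TPM with the drug (log2 fold change 2.67, SE 0.28, adjusted p = 0.0037). Transcript uc033jnf.1 had 6.81, 5.52, 10.2 and 28.0 TPM in KO DMSO and was listed at 0 in all 4 KO rosiglitazone libraries (log2 fold change -3.50, SE 0.37, adjusted p = 0.0037). Transcript uc007fmp.1 rose from 0.027 ± 0.012 TPM to 2.85 ± 0.98 TPM (SD, n = 4 each; log2 fold change 1.86, SE 0.26, adjusted p = 0.0384). In WT it measured 3.36 ± 0.57 TPM in DMSO and 4.04 ± 2.19 TPM in rosiglitazone (SD, n = 3 each), and the difference between the genotypes in its response did not pass (1.73 on the log2 scale, SE 0.39, adjusted p = 1.00). Transcript uc009bev.1 fell from 3.38 ± 0.83 TPM to 0.0011 ± 0.0015 TPM (SD, n = 4 each; log2 fold change -2.11, SE 0.24, adjusted p = 0.0070), and its interaction did not pass either (-1.77, SE 0.37, adjusted p = 1.00). With the number range as a covariate 7 transcripts passed, and 7 also passed without the libraries numbered 18 to 21, 1 of them among the 4. The count was 2 without KO DMSO replicate 4 and 8 without KO rosiglitazone replicate 1. Leaving out KO DMSO replicate 4 ended the call of uc009bev.1, and 11 of the 14 libraries, all but WT rosiglitazone replicates 1 and 3 and KO rosiglitazone replicate 2, each ended that of uc007fmp.1 when left out. Of 17 alternative settings, 5 ended the call of uc033hga.1, 3 that of uc033jnf.1, 8 that of uc007fmp.1 and 4 that of uc009bev.1.

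Averaged over both genotypes, the response to rosiglitazone passed the threshold for 1 transcript. Transcript uc008mgk.1 fell with the drug. It had 1.29, 2.46 and 1.79 TPM in WT DMSO and at most 0.0715 TPM in WT rosiglitazone. In KO it had 2.86, 3.39, 0.84 and 2.31 TPM in DMSO, and with the drug it was listed at 0 in 2 libraries and was at most 0.0081 TPM in the others (average log2 fold change -1.55, SE 0.19, adjusted p = 0.0476). The higher transcripts with the smallest p did not pass. Transcript uc008opl.2 measured 87.7 ± 19.2 TPM in WT DMSO and 460 ± 84.7 TPM in WT rosiglitazone (SD, n = 3 each). In KO it measured 89.4 ± 34.0 TPM and 187 ± 74.4 TPM (SD, n = 4 each). Its average log2 fold change was 1.72 (SE 0.23, adjusted p = 0.0608). Within KO alone the change was 1.05 among the libraries with sample numbers up to 5 and 1.06 among those numbered 18 to 21. Transcript uc008tlz.1 measured 30.2 ± 0.80 and 59.3 ± 10.0 TPM in WT (SD, n = 3 each) and 29.2 ± 5.35 and 51.3 ± 10.1 TPM in KO (SD, n = 4 each), an average log2 fold change of 0.87 (SE 0.12, adjusted p = 0.0730). Of 17 alternative settings, 8 brought uc008opl.2 past the threshold (adjusted p from 8.5e-05 to 0.119 over the 17) and 5 did so for uc008tlz.1 (0.0067 to 0.119). With the number range as a covariate the adjusted p was 8.5e-05 and 0.0086, and without the libraries numbered 18 to 21 it was 0.0328 for uc008opl.2 and 0.0999 for uc008tlz.1. Leaving out 1 library also brought uc008opl.2 past the threshold for WT rosiglitazone replicate 3, KO DMSO replicate 2 and KO rosiglitazone replicates 3 and 4, and uc008tlz.1 for KO DMSO replicate 2 and KO rosiglitazone replicate 3. The number at an unadjusted p under 0.05 was 1867, against 1465 expected by chance, an excess that was not tested. The count was 0 with median-of-ratios scaling (2007 at an unadjusted p under 0.05) and with quantile normalization (2010). Leaving out single libraries gave 5 (KO rosiglitazone replicate 1 or 3), 6 (KO rosiglitazone replicate 4), 8 (WT rosiglitazone replicate 3) or 9 calls (KO DMSO replicate 2), and 0 without WT DMSO replicate 2 (1551 at an unadjusted p under 0.05) or 3 (1341), WT rosiglitazone replicate 1 (1487) or 2 (1517), KO DMSO replicate 1 (1880) or 4 (1724), or KO rosiglitazone replicate 2 (1683). The replicate numbers were not taken as pairs, for reasons given below. As a random block they gave 74 calls, 28 higher and 46 lower, with 3530 transcripts at an unadjusted p under 0.05. As a fixed block they gave 1, which was uc008opl.2 (adjusted p = 0.0233), with 3638 at an unadjusted p under 0.05. The call of uc008mgk.1 ended in 6 of 16 alternative settings. It also ended without WT DMSO replicate 1, 2 or 3, WT rosiglitazone replicate 1 or 2, KO DMSO replicate 1 or 4, or KO rosiglitazone replicate 2.

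**Figure D2:**
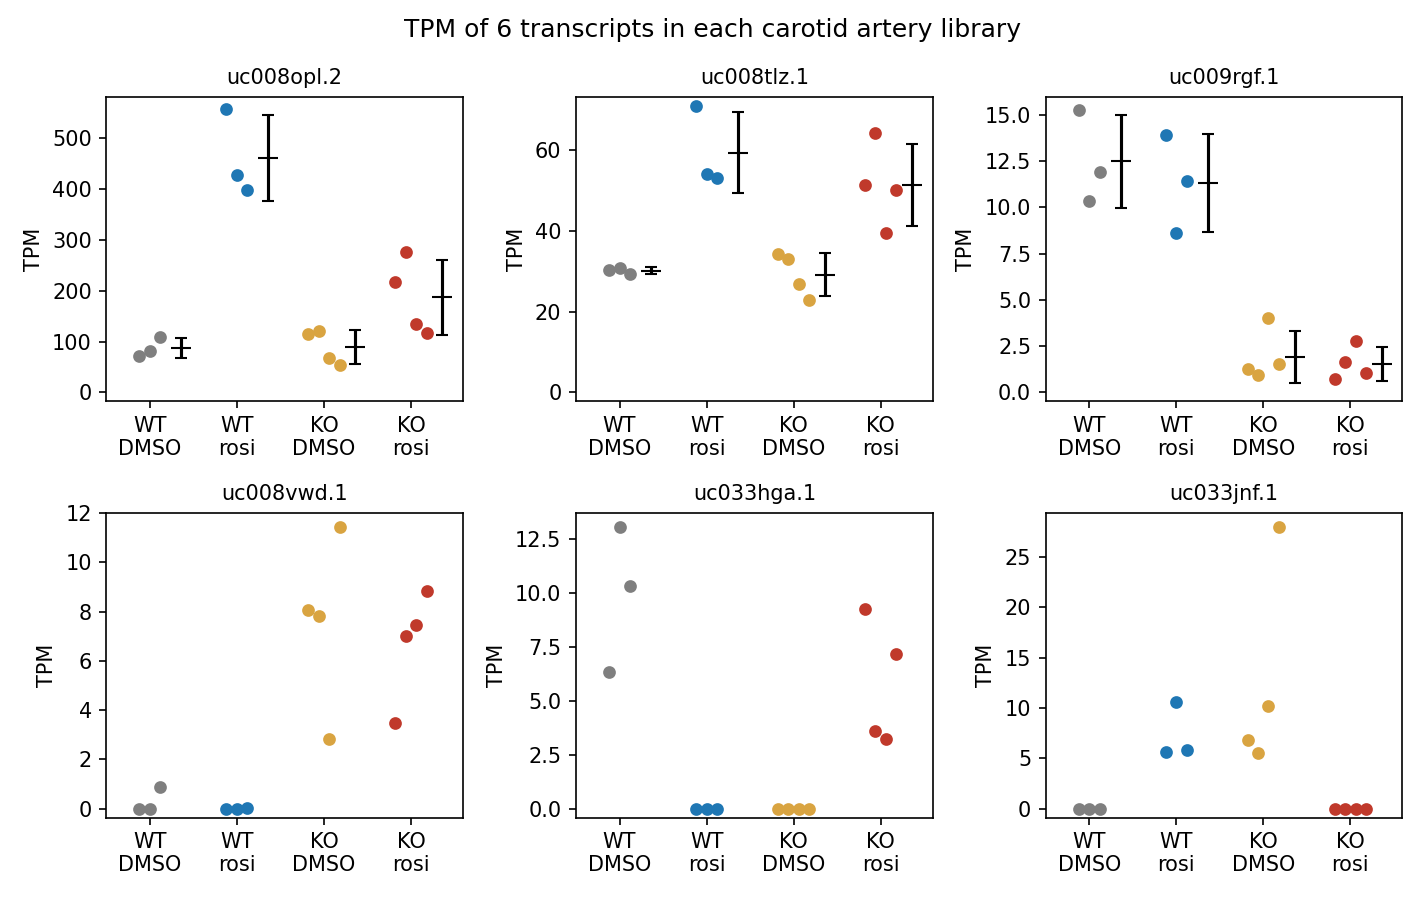
TPM (y axis, linear) of 6 transcripts in the 4 groups (x axis), 1 point per library; where no group holds a 0, the black mark and bar give the mean and SD of the group. Transcript uc008opl.2 averages 460 TPM in WT rosiglitazone and 187 TPM in KO rosiglitazone, and uc033hga.1 and uc033jnf.1 are listed at 0 in opposite groups.

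Whether the response differed between genotypes was tested as the interaction. The 2 transcripts that passed were uc033hga.1 (log2 difference of the KO and WT responses 6.06, SE 0.42, adjusted p = 5.5e-05) and uc033jnf.1 (log2 difference -6.52, SE 0.56, adjusted p = 0.00035). Each library listed one of this pair above 0 and the other at 0, and the total of both ranged from 3.24 to 28.0 TPM. The interaction of that total was -0.45 (SE 0.66) on the log2 scale. For uc008opl.2 the response was 2.39 (SE 0.35) in WT and 1.05 (SE 0.30) in KO on the log2 scale, a difference of -1.33 (SE 0.46) that did not pass (adjusted p = 1.00). For uc008tlz.1 the difference was -0.15 (SE 0.24, adjusted p = 1.00). At an unadjusted p under 0.05 there were 627 transcripts. The count was 4 without WT DMSO replicate 1 and 6 without KO rosiglitazone replicate 4. It was 0 (522 at an unadjusted p under 0.05) when transcripts listed at 0 in 3 or more libraries were left out, a choice made after seeing the data. That filter takes out both called transcripts before testing, so the loss of these 2 calls was fixed in advance.

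The genotypes were then compared within each treatment. In DMSO, 15 transcripts differed between KO and WT, 7 higher and 8 lower in KO. In rosiglitazone 12 differed, 4 higher and 8 lower. The 2 comparisons share no libraries, and in the fit over all libraries 10 transcripts passed in both, 8 of them with the same sign (3 higher and 5 lower in KO). The comparisons share 1 estimate of the spread, however. They may also share animals, because the labels do not say whether a replicate number marks an animal. When each comparison was fitted on its own 2 groups, 15 and 12 transcripts passed, of which 2 passed in both, with the same sign, and 6 and 4 were among those called above. Of the 25 transcripts called in either separate fit, 16 had the same sign in both, against 14 of 17 in the fit over all libraries. These counts of separate fits were made after seeing the data. The 2 of opposite sign in the fit over all libraries were uc033hga.1 and uc033jnf.1. The distinct rows were 14 and 11, because 2 of the called transcripts, both lower in KO, had identical values in every library.

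Among transcripts of the same sign in both treatments, uc008vwd.1 was higher in KO. It had 8.07, 7.84, 2.83 and 11.4 TPM in KO DMSO and 3.49, 7.03, 7.45 and 8.85 TPM in KO rosiglitazone, while the highest WT value was 0.87 TPM. Its log2 fold change was 2.67 in DMSO (SE 0.38, adjusted p = 0.0178) and 2.88 in rosiglitazone (SE 0.38, adjusted p = 0.0123). Transcript uc009rgf.1 was lower in KO, with 1.93 ± 1.40 TPM (SD, n = 4) against 12.5 ± 2.51 TPM (SD, n = 3) in DMSO and 1.54 ± 0.90 TPM (SD, n = 4) against 11.3 ± 2.64 TPM (SD, n = 3) in rosiglitazone. Its log2 fold changes were -2.29 (SE 0.33, adjusted p = 0.0187) and -2.31 (SE 0.33, adjusted p = 0.0234). With the number range as a covariate both calls of uc008vwd.1 ended (log2 fold change 2.62, SE 0.43, adjusted p = 0.105 in DMSO and 2.82, SE 0.43, adjusted p = 0.0661 in rosiglitazone). Without the libraries numbered 18 to 21 its call in rosiglitazone ended (log2 fold change 2.58, SE 0.33, adjusted p = 0.0613). Over all settings other than left-out libraries, its calls ended in 7 and 5 of 17 (adjusted p from 0.0069 to 0.194 and from 0.0031 to 0.106), and those of uc009rgf.1 in 6 and 7 of 18 (0.0061 to 0.141 and 0.0106 to 0.189). Leaving out 1 library ended each of these calls in 5 or 6 of 14 cases. For uc008vwd.1 these were WT replicates 1 and 2 and KO replicates 1, 2 and 4 in DMSO, and WT replicates 1, 2 and 3 and KO replicates 3 and 4 in rosiglitazone. For uc009rgf.1 they were WT replicates 1, 2 and 3 and KO replicates 1, 2 and 4 in both treatments.

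At an unadjusted p under 0.05 there were 1063 transcripts in DMSO and 848 in rosiglitazone. The DMSO split was 7 higher and 11 lower with median-of-ratios scaling, and 6 higher and 11 lower with quantile normalization. The DMSO count was 9 without WT DMSO replicate 2. The rosiglitazone count was 2 without WT rosiglitazone replicate 1, 4 without replicate 2, 4 without replicate 3 and 7 without KO rosiglitazone replicate 3. Sample numbers 18 to 21 occur only among KO libraries. The lower numbers do not mix the genotypes either, since 2 to 5 are KO and 6 to 11 are WT. Genotype thus cannot be told apart from sample number, and neither leaving libraries out nor a range covariate can part them. Without the 4 libraries numbered 18 to 21 the counts were 15 in DMSO and 14 in rosiglitazone. Of these, 10 and 7 were among the transcripts called with all libraries. The split was then 4 higher and 11 lower in DMSO and 1 higher and 13 lower in rosiglitazone. A pseudocount of 5 also gave 1 higher and 11 lower in rosiglitazone.

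**Figure D3:**
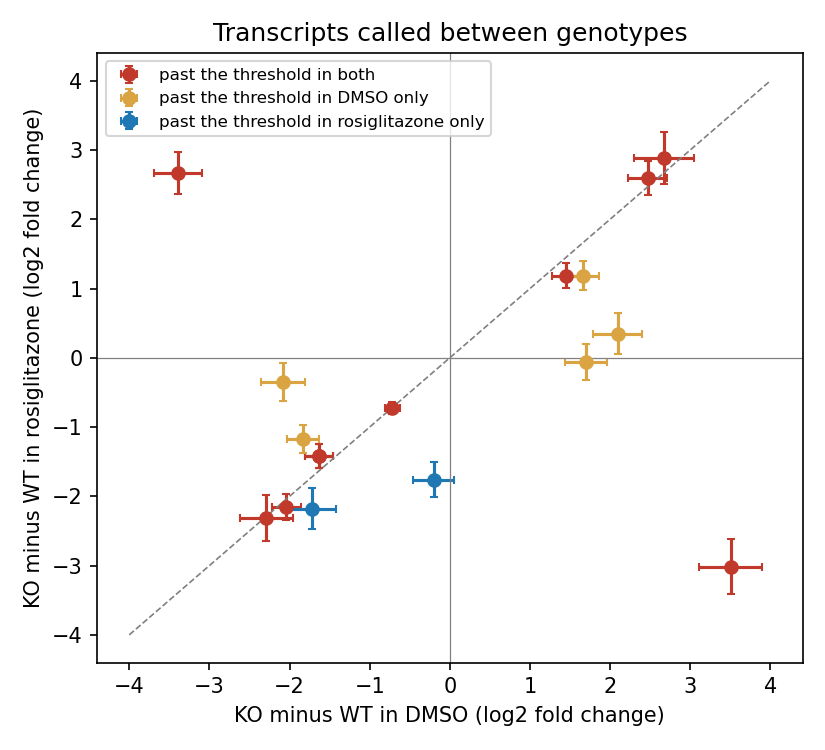
Log2 fold change of KO against WT in DMSO (x axis) and in rosiglitazone (y axis) for the 17 transcripts past the threshold in either comparison, with bars of 1 SE; color gives where each passed and the dashed line marks equal values. In this fit over all libraries the signs are alike for 14 of the 17 transcripts, 2 of which have identical values. The pair with the largest opposite changes lies in the upper left and lower right.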

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

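Of the tests below, those of all-or-none assignment, of chance placement along the identifiers, of DNA around the deleted gene and of the sample-number range were chosen after the results were seen, and so was the outlier check's list of transcripts. In 30 sets of 4 KO values, the gap of 1 library to its nearest neighbour was compared with the range of the set. Dixon's critical value for 4 samples was passed by 6 sets. Chance gives about 1 set in 20, but several sets describe the same library, so the 6 cannot be set against that rate. In KO DMSO, replicate 4 stood apart in the number of transcripts at 1 TPM or more (ratio 0.875), on the first principal component (0.893) and in its median Spearman correlation with the other libraries (0.896). In KO rosiglitazone, replicate 4 stood apart on the first component (0.983). For uc007fmp.1 in KO DMSO the ratio was 0.967, from 0.046 TPM in replicate 4 against at most 0.022 TPM in the others. For uc009bev.1 in KO rosiglitazone it was 0.846, from 0.0033 TPM in replicate 4 against at most 0.00051 TPM.

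Both KO libraries of replicate number 4 thus lay away from the other 12. Scaling by the most abundant transcripts predicts that a rescaled table brings them back. After median-of-ratios scaling the nearer of the pair still lay 1.38 times as far out on the first component as the farthest other library, against 1.71 times as deposited, which argues against scaling as the whole cause. A batch shared by sample numbers 18 to 21 predicts that the KO libraries of replicate number 3 lie beyond every library numbered 2 to 11, on the same side. In the values as deposited, 0 of these 2 libraries did. After median-of-ratios scaling 1 of them did. After quantile normalization 2 did, at 20.4 and 6.57 against at most 4.55 in the libraries numbered 2 to 11. The libraries of replicate number 4 then lay at 67.3 and 48.8, so those of replicate number 3 did not reach them. The 2 ranges also differed within KO in 140 transcripts, so a batch stays open. A property of tissue or library preparation shared by the number 4 remains open, and no biological explanation was tested.

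A difference between genotypes in the response to rosiglitazone was called for uc033hga.1 (log2 difference 6.06) and uc033jnf.1 (log2 difference -6.52). The file holds 537 transcripts that are at 0 in 3 to 11 libraries and at 1 TPM or more in all others, and 535 of them (99.6%) split the replicates of a group. With minimums of 2 and 3 TPM, also looked at, 386 of 388 and 309 of 311 did. All-or-none assignment of shared reads between similar transcripts would give this. Almost any other source of zeros would too, because few patterns of zeros follow the groups, so this share cannot decide. In 10000 shuffles of the group labels, 30.0% gave 2 or more such transcripts that followed group boundaries. The shuffles counted any pattern that was alike in all replicates of each group. They did not ask for 2 opposite patterns, as in this pair. That is a narrower event, so this share does not give how often chance would produce it. An assignment artifact that fell on the groups by chance is a candidate explanation. How often chance would give such a pair, and whether the 2 transcripts share reads, was not tested. A switch between related transcripts that depends on genotype and drug is not excluded.

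Transcripts called between KO and WT lay close together in identifier order. Of the 16 distinct ones, 6 fell within 89 consecutive tested transcripts, 3 higher and 3 lower in KO in both treatments. In a permutation test, none of 10000 random placements put 6 in a window of 100, a width set after the stretch was seen (permutation p = 0.0001, the smallest they can give; highest 4). Over 6 widths from 20 to 1000 the p was 0.0001 as well, and it was 0.0008 with calls up to 10 ranks apart counted once, which argues against chance placement. Counting calls up to 20 ranks apart once gave 0.348, but this chains the 6 into 2 items and cannot test the stretch. Whether neighbours share reads was not tested. All 6 kept their direction and an unadjusted p under 0.05 in both treatments without the libraries numbered 18 to 21, so these libraries are not the whole cause. Among the other 83 transcripts of the stretch, 20.5% had an unadjusted p under 0.05 in DMSO, against 3.63% of all tested. If identifiers follow genome order, DNA of another strain kept around the deleted gene might give such a stretch, as might an effect of the deletion on its neighbours. These cannot be told apart here, because 0 of the 63244 identifiers were matched to a table that gives chromosomes.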

How the results depend on the processing

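The same-sign shares and the alternatives on transcripts over 5000 TPM, identical rows, transcripts listed at 0 and replicate number 4 were chosen after seeing the data. KO against WT in DMSO stayed within 1.5 times its count of 15 in all 18 alternatives that did not leave out single libraries (10 to 21 calls, 6 to 15 of them shared). In rosiglitazone the count of 12 did so in 17 of 18 (9 to 17), the exception being the fixed replicate block. The counts stayed within 1.5 times in 4 of 18 alternatives for rosiglitazone in WT, 10 of 18 in KO, 4 of 17 on average and 10 of 17 for the interaction. None of the named transcripts changed sign under any alternative.

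Counts are given for rosiglitazone in WT, in KO, on average and for the interaction, where they moved by over 1.5 times from 1, 4, 1 and 2; the cause was not tested. A pseudocount of 0.1 gave 3 in WT, 5 on average and 4 for the interaction, and one of 5 gave 2 in WT, 2 in KO, 0 on average and 1 for the interaction. Testing transcripts above 0 in any library gave 5, 2 and 5 for WT, average and interaction. A minimum of 5 TPM gave 0 in WT, 1 in KO and 0 on average. Median-of-ratios scaling and quantile normalization gave 2 in WT and 0 on average. Robust variances gave 0 on average. Library weights gave 5 in WT and 9 on average. Fits on the groups compared alone gave 5 in WT and 2 in KO. Without libraries numbered 18 to 21 the counts were 7, 7, 4 and 6, and with the number range as a covariate 4 in WT, 7 in KO and 6 on average. Removing transcripts over 5000 TPM gave 3 in WT. Leaving out transcripts listed at 0 in 3 or more libraries gave 0, 1, 4 and 0. This filter removes uc033hga.1 and uc033jnf.1, so the loss of their calls was fixed in advance. Without both KO libraries of replicate number 4 the counts were 6 in WT, 4 on average and 5 for the interaction. Beside limma's counts of 0, the transcripts at an unadjusted p under 0.05 numbered 453 and 927 in WT (minimum of 5 TPM, zeros left out) and 522 for the interaction. On average they numbered 1836, 949, 2007, 2010 and 1869 (pseudocount of 5, minimum of 5 TPM, median-of-ratios, quantile, robust).

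Replicate numbers were tried as a block. The fixed rule for taking the numbers as pairs was a correlation over 0.1 in all 7 pairs, between deviations from the group means. Same-numbered libraries had correlations of 0.072 to 0.219, over 0.1 in 4 of 7 pairs, so the numbers were not taken as pairs. Missing this rule does not exclude pairs. As a hint from the data, 10 of 14 libraries correlated best with their own number, and same-numbered libraries of a genotype carry adjacent sample numbers. The libraries that did not were KO replicates 1 and 2, numbered 2 to 5, where correlations with another number reached 0.109. A difference between the sample-number ranges within KO could raise those correlations, which was not tested. If the numbers do mark pairs, the rosiglitazone tests without a block ignore them. A fixed replicate block gave 1, 0 (2919 at an unadjusted p under 0.05), 1 and 2, and 11 and 7 for KO against WT in DMSO and rosiglitazone. The 1 in WT and the 1 on average were other transcripts than in the fit without the block, and higher with the drug: uc033hga.1 in WT went to adjusted p = 0.0562 and uc008mgk.1 on average to 0.0936, while uc008opl.2 passed on average (0.0233). It also ended the calls of uc008vwd.1 (0.148 in DMSO, 0.106 in rosiglitazone) and uc009rgf.1 (0.0798 and 0.0977). A random replicate block with a consensus correlation of 0.342 gave 5, 11, 74 (28 higher and 46 lower) and 4, and 14 and 13.

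Leaving out single libraries gave 1 to 3 calls in WT, 2 to 8 in KO, 0 to 9 on average, 2 to 6 for the interaction, 9 to 17 in DMSO and 2 to 16 in rosiglitazone. Among the named transcripts, 62 of their values lost the threshold and 27 gained it over the other alternatives, and 250 did neither. The same-sign share passed an exact p of 0.05 with the top 500 (69.8%) when picked in WT, and with the top 100 (78.0%) or median-of-ratios scaling (78.5%) when picked in KO against WT under rosiglitazone. Gene sums, gene list tests and the removal of mitochondrially encoded genes were not run, since they need gene names. Depth is unknown and sets no stated limit.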

Other observations

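All tests of shared direction, and the comparison of sample-number ranges, in this part were chosen after seeing the data; the counts of splits were planned. To see whether the genotypes responded alike below the threshold, the 200 transcripts with the smallest p for rosiglitazone in WT were read in KO, which shares no libraries with WT, although the spread used for ranking was estimated over both. Their sign was the same for 69.5%, with a median change of 0.22 in that direction on the log2 scale. As many or more agreed in 4 of the 70 labelled splits of the KO libraries (exact one-sided permutation p = 0.0571, 0.0762 after adjustment over the 4 readings; highest other 76.5%). Picked in KO and read in WT, 72.5% had the same sign, more than in any other of the 20 labelled splits (exact one-sided permutation p = 0.05, the smallest possible, adjusted 0.0762; highest other 67.0%).

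For genotype, transcripts picked in DMSO had the same sign in rosiglitazone for 63.0% (exact one-sided permutation p = 0.171, adjusted 0.171; highest other 68.0%). Transcripts picked in rosiglitazone had it in DMSO for 74.0% (exact one-sided permutation p = 0.0571, adjusted 0.0762; highest other 75.0%). The DMSO and rosiglitazone libraries of a genotype may come from the same animals, which could raise such agreement. None of the 4 readings passed after adjustment. The one picked in KO and read in WT could not have passed, because its 20 splits give no p under 0.05.

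Other splits of the same libraries were counted for each contrast. For rosiglitazone in WT, the real count was 1 and the highest of the others 5; 6 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. For rosiglitazone in KO, 2 of 35 splits gave 4 or more, so chance is not excluded. The other one reached 140, and it parts the libraries numbered 2 to 5 from those numbered 18 to 21. It points to a structure of the samples that follows the sample numbers, with 63 transcripts higher and 77 lower in 18 to 21. The count for rosiglitazone in KO was 7 with the number range as a covariate. On average, 51 of 100 drawn splits gave 1 or more (highest other 22). For the interaction 26 of 100 gave 2 or more (highest other 19), so chance is not excluded for either count. These splits ignore the replicate numbers. With those as a random block 74 transcripts passed on average and 4 for the interaction. For KO against WT, only the real one of 35 splits reached 15 in DMSO (highest other 3) and 12 in rosiglitazone (highest other 4). For both counts the real split's share of 2.86% is the smallest that 35 splits can give. It is under 0.05 but was not adjusted over the 6 contrasts, so chance is less likely but not excluded. Genotype also follows sample number, so these counts cannot be credited to genotype alone.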
